A study of Mus musculus with 2 samples.

How the data were processed

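The series holds 1 pooled suspension of mouse heart cells other than cardiomyocytes, taken 7 days after TAC (transverse aortic constriction, a surgical narrowing of the aorta that overloads the left ventricle). Per the labels, cells of 3 control mice and 4 Nts knockout mice carried a different hashtag antibody per mouse, and viable cells (stained by calcein-AM, not by DAPI) from all mice were pooled by sorting and loaded on a 10x 3′ version 3.1 kit with a target of 10000 cells. The pool gave a gene expression library and a hashtag library. The deposited matrix is the gene expression library and holds whole-number UMI counts (unique molecular identifiers, each standing for a captured transcript) without normalization. STARsolo, Scanpy and the mm10 build are named in the submitters' processing notes without version or settings, so the rule that called the deposited barcodes as cells is not known. The features are 56953 genes and the CreERT2 transgene, with no hashtag among them.

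The study names a comparison of control with knockout mice. It could not be run here because nothing used here ties a cell to a mouse, and no split of the cells stands in for it. Genotype was not inferred from Nts, from CreERT2 or from any other transcript. The hashtag library was not analysed here.

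Analyses used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and umap-learn 0.5.12, and figures matplotlib 3.10.9. A filter of at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs removed 0 barcodes. Scrublet, as built into scanpy, called 357 doublets (3.81%), which were removed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after the functional list genes, mitochondrial genes and ribosomal protein genes had been set aside. Clusters came from 30 principal components, 15 neighbours and Leiden resolution 1 with a fixed seed, and were numbered by size.

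Each cluster was classed by 20 marker lists holding 172 genes, for fibroblasts, blood endothelial, lymphatic endothelial and endocardial cells, pericytes, smooth muscle, Schwann cells, mesothelial or epicardial cells, macrophages, monocytes, dendritic cells, neutrophils, mast cells, B cells, T cells, NK or innate lymphoid cells, cardiomyocytes, adipocytes, erythroid cells and platelets or megakaryocytes. A marker counted as detected at 50 CPM (UMIs of a gene scaled to the total UMIs of the cells) or more and at least 25% of its highest cluster. The class was the list with the largest share of its markers detected, and at least 3 of them. A cluster was called mixed and left in no class where a list of another lineage also had at least 50% of its markers detected, or held 3 or more (and more than the leading list) of the 10 genes with the largest fold over the other cells (10 CPM added to each side). A cell type name was kept where those 10 genes held no more markers of any other list than of its own. Classes that passed are written as "-like", and those that failed are given by cluster number. The thresholds of this rule were set after the data had been seen.

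For each class, UMIs were summed over its cells and expressed as CPM of the class total, with 95% exact Poisson intervals. A ratio between classes has a 95% exact interval from the binomial distribution of its pair of sums. Shares of cells have 95% Clopper-Pearson intervals. These intervals cover counting error only. With 1 pooled library there is no replicate, cells are not replicates, and no significance test was run. Shares of cells with a UMI were computed after each cell had been thinned at random to 1500 UMIs, so that depth did not differ between classes. A count of 0 was set against a floor of 3 counts over the class.

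Before the data were examined, 17 functional lists of 8 to 30 genes (314 genes) were fixed: the neurotensin system, extracellular matrix and fibrosis, chemokines, inflammatory cytokines and mediators, type I interferon response, MHC class II presentation, complement, angiogenic and lymphangiogenic ligands and receptors, vasoactive and natriuretic signalling, TGF-beta and BMP signalling, growth factors, Wnt signalling, leukocyte adhesion and trafficking, cell cycle, hypoxia and glycolysis, immediate early and dissociation response, and lipid uptake and handling. A list gene with at least 20 UMIs over both sides was called higher on a side when its ratio was at least 2 and its interval excluded 1. The rule for named genes was fixed at the same time. It takes Nts, Ntsr1, Ntsr2 and Sort1 in every comparison. To these it adds the called genes with the largest ratio on each side, at most 2 per side and list, up to 30 genes in all, without the marker genes. Across classes it takes, for each list, the 2 genes with most UMIs in the class where the list sums highest. The median log2 ratio of a list (1 CPM added to each side) was placed among 10000 random lists of the same size matched on mean expression, as a description of this library.

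The procedure was tested on simulated counts with 200 genes changed by a known fold. Of genes changed 3-fold, 86.6% of 67 were called in the right direction for lymphatic against blood endothelial cells, 97.9% of 47 for fibroblasts against all other cells and 97.2% of 71 for macrophages against monocytes. Among unchanged genes, 1.53%, 0.469% and 0.820% were called in the same order of comparisons. Counts were drawn independently from a shared profile, without clustering, free RNA, doublets or UMIs gathered in few cells. These rates are therefore not rates of false calls in the data. Of 200 lists of unchanged genes, 8%, 7% and 6.5% fell outside the 2.5th to 97.5th percentile, so even in this simulation list percentiles reached the tails too often. Genes of a list can vary together between cell classes, which independent draws leave out. How often percentiles reach the tails in the data is therefore not known. The alternatives were no or a stricter cell filter, doublets kept, other variable genes, other resolutions, fewer principal components, other normalizations, other thinning depths and other minimums for cycling cells. Another random seed and other treatments of the mixed clusters, of cluster 12 and of fibroblast clusters were added after the data had been seen.

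Gene positions are from GENCODE M21 on GRCm38, the assembly also called mm10. Of the 56953 gene identifiers, 52029 (91.4%) are in that release. Reads of near-identical gene copies (Ifit3 with Ifit3b, Hspa1a with Hspa1b, Ccl21a with its copies) can be split or lost in counting, so levels of these genes are uncertain.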

Results

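The data are 1 gene expression library of pooled heart cells, without replicate, from 3 control and 4 Nts knockout mice 7 days after TAC. The deposited matrix held 69993559 UMIs in 9369 barcodes, beside the 10000 cells aimed at, with 2567 to 42567 UMIs per barcode and a median of 6663. The median barcode had 2485 detected genes and 0.733% mitochondrial UMIs. After 357 called doublets were removed, 9012 cells with 65360456 UMIs remained in 31 clusters. Cells were not tied to mice, so the comparison of control with knockout hearts named by the study was not made. The pool is described with both genotypes while the genotype entry of both libraries reads WT, a conflict left open here. The comparisons are between cell classes of the pool, and if both genotypes are in it, every value is an average over them in unknown proportions.

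Fibroblast-marker cells made up most of the analysed pool. Shares describe a sorted suspension of viable cells, not the make-up of the tissue. The series holds no unoperated hearts, so no share or level here can be tied to overload. Clusters 1, 2, 3, 4, 6, 7 and 19 had at least 7 of the 10 fibroblast markers detected, Pdgfra and Dcn among them. None of these markers was among their 10 leading genes by fold over the other cells. The 7 clusters held 4765 cells, 52.9% of the cells analysed (51.8 to 53.9%). Macrophage-like cells were next with 1846 cells (20.5%, 19.7 to 21.3%), followed by 417 monocyte-like cells (4.63%) and 377 T cell-like cells (4.18%). The vessel lining was split into 220 blood endothelial-like cells (2.44%, 2.13 to 2.78%), 219 cells of cluster 12 (2.43%) and 70 lymphatic endothelial-like cells (0.777%, 0.606 to 0.980%). Cluster 12 had all 7 endocardial markers detected, including Npr3, but failed the name check because 3 of its leading genes were blood endothelial markers. Smaller classes were 193 dendritic cell-like, 171 B cell-like, 117 NK or innate lymphoid-like, 39 pericyte-like, 29 mesothelial or epicardial-like and 24 smooth muscle-like cells. Another 525 cells (5.83%) lay in 6 mixed clusters that carried markers of more than a single lineage.

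No cluster was classed under the other marker lists. Cells with at least 3 detected markers numbered 303 for neutrophils, 38 for cardiomyocytes, 25 for Schwann cells, 13 for platelets or megakaryocytes, 9 for mast cells, 3 for erythroid cells and 0 for adipocytes. Neutrophil markers led the mixed cluster 18 (153 cells), which also carried fibroblast markers. The fibroblast clusters 1, 3 and 19 failed the name check, so the class is called fibroblast-marker rather than fibroblast-like. Fibroblast clusters 2, 4, 6 and 7 and macrophage-like clusters 8, 23 and 25 passed it with no marker of any list among their leading genes. For them the check adds nothing to the detected markers.

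**Figure D1:**
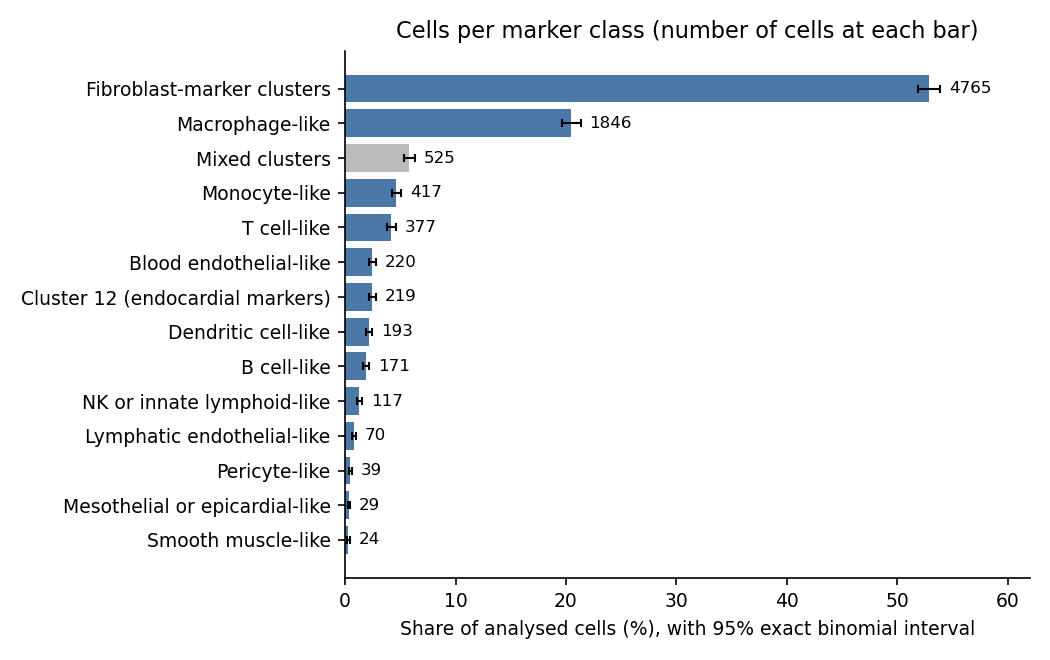
Share of the 9012 analysed cells in each marker class, in percent, with 95% exact binomial intervals and the number of cells at each bar. The fibroblast-marker clusters hold 52.9% and the lymphatic endothelial-like class 0.777%.

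Neurotensin transcripts were concentrated in endothelium, and its classical receptors were nearly undetected in the pool. Nts, which encodes the neurotensin precursor (ENSMUSG00000019890, chromosome 10, 102481756 to 102490486 on the minus strand, GRCm38), gave 1595 UMIs in 195 cells. The 3 endothelial classes held 94.98% of them. Its level was 1139 CPM in lymphatic endothelial-like cells (1033 to 1254), 569 CPM in cluster 12 (531 to 610) and 241 CPM in blood endothelial-like cells (214 to 270). All cells outside these classes together had 1.28 CPM (1.02 to 1.60). After thinning to equal depth, Nts was detected in 28.6% of lymphatic cells (18.4 to 40.6%), 23.3% of cluster 12 and 10.0% of blood endothelial-like cells, against 0.153% of the remaining cells, which mark the background. Median depths before thinning were 5064.5, 5369, 4532 and 6663 UMIs in that order. Nts was uneven within each class: 46 of the 70 lymphatic cells had no Nts UMI, while 11 cells with 10 or more held 88.2% of the lymphatic total. The pool mixes control and knockout mice, so the Nts-free cells were not read as a knockout fraction.

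The G protein-coupled receptor Ntsr1 had 0 UMIs in 9012 cells, which allows up to 0.0564 CPM. Ntsr2 had 1 UMI. Sort1, which encodes sortilin, a sorting receptor that also binds neurotensin, had 546 UMIs (8.35 CPM over all cells). Sort1 was 10.1 CPM in fibroblast-marker clusters (9.16 to 11.2), 17.6 CPM in monocyte-like cells (12.8 to 23.6) and 3.02 CPM in macrophage-like cells (2.11 to 4.21). Smooth muscle-like cells had 70.9 CPM of Sort1 from 9 UMIs (32.4 to 135), and the lymphatic class had 0 UMIs. In the lymphatic class 3 UMIs are already 8.10 CPM, so a Sort1 level near that of all cells is not excluded there. Among the peptidases of the list, Mme, which encodes neprilysin, was 23.3 CPM in fibroblast-marker clusters against 0.605 CPM in macrophage-like cells and 1 UMI in blood endothelial-like cells. Nln (neurolysin), Thop1 and Prep were spread over the classes at 17.1, 10.1 and 11.6 CPM over all cells. Among processing enzymes, Furin reached 46.1 CPM over all cells, whereas the neuroendocrine convertases Pcsk1 and Pcsk2 gave 16 and 12 UMIs.

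**Figure D2:**
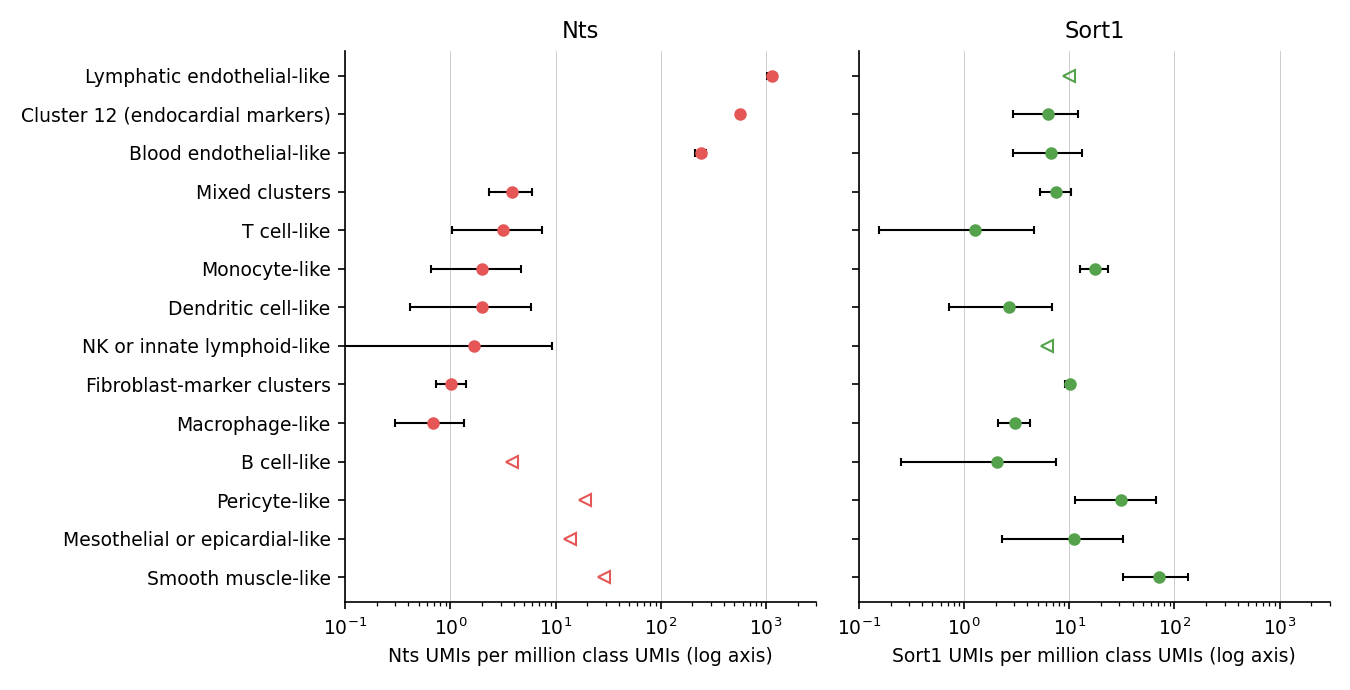
Nts and Sort1 level per marker class on a log axis, in CPM, with 95% exact Poisson intervals; open triangles mark the upper limit of classes with 0 UMIs. Nts is 1139 CPM in lymphatic endothelial-like cells and 1.02 CPM in fibroblast-marker clusters, while Sort1 is highest in smooth muscle-like cells at 70.9 CPM.

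Lymphatic against blood endothelial-like cells compares 2 of the 3 classes that held Nts: of its 1595 UMIs, cluster 12 held 807, the lymphatic class 422 and the blood endothelial-like class 286. Single genes led the lymphatic side, without a lean of their lists: Ptn (pleiotrophin) was 39.6-fold higher (22.0 to 78.3), Sema3d 34.1-fold (16.5 to 81.5) and Sema3a 21.9-fold (9.25 to 63.2), the last a repulsive cue of the semaphorin family. Nts was 4.73-fold higher (4.06 to 5.52). This interval covers counting error only, and few cells carry the counts. Cells with 10 or more Nts UMIs were 11 of 70 lymphatic cells, with 88.2% of the class total, and 6 of 220 blood endothelial-like cells, with 65.0%. In every alternative that clustered the cells anew the Nts ratio was below this interval, down to 2.72-fold at Leiden resolution 0.5, so its size depends on the clustering. Blood endothelial-like cells had more of Tcf15 and Meox2, partner transcription factors of fatty acid uptake in heart capillaries, by 161-fold (28.7 to 6355) and 73.0-fold (13.0 to 2894), each against 1 lymphatic UMI. Of the 202 list genes with enough UMIs, 40 were higher in lymphatic cells, 70 higher in blood endothelial-like cells and 92 neither. Another 112 had too few UMIs.

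By list, 16 of 18 measured cell cycle genes were higher in blood endothelial-like cells and 0 in lymphatic cells, for example Pclaf, a partner of the replication clamp, at least 4.78-fold against the floor (interval from 3.73), and Ccnb1 at least 2.08-fold (interval from 1.54, under 2-fold). These calls can share the same few cells and are not 16 separate pieces of evidence. At equal depth, 29 of 220 blood endothelial-like cells (9.01 to 18.4%) had at least 2 UMIs over this list. So did 3 of 70 lymphatic cells (0.893 to 12.02%), and the 2 intervals overlap. Of 13 lipid genes, 6 were higher in blood endothelial-like cells and 1 in lymphatic cells. Of 22 matrix genes, 7 were higher in blood and 3 in lymphatic cells, and the summed matrix level was 9072 against 2506 CPM. The collagen crosslinkers parted: Loxl2 was 8.11-fold higher in lymphatic cells (4.53 to 15.2), and Lox at least 3.33-fold higher in blood endothelial-like cells (interval from 2.55). Among 23 angiogenic genes, 7 were higher on each side. The apelin pair was on the blood side, Aplnr at least 29.8-fold (interval from 24.1) and Apln at least 8.42-fold (interval from 6.69).

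Chemokines were also divided, with 3 of 13 higher in lymphatic and 6 in blood endothelial-like cells. Cxcl12, the ligand of Cxcr4, was 104-fold higher in blood endothelial-like cells (40.3 to 381) and the interferon-inducible Cxcl9 at least 16.8-fold (interval from 13.5), whereas Cxcl14 was 17.3-fold higher in lymphatic cells (6.57 to 57.6). Of 11 leukocyte adhesion genes, 6 were higher in blood endothelial-like cells, among them the junctional protein gene Jam2 (122-fold, 21.7 to 4816, against 1 lymphatic UMI) and E-selectin, Sele (at least 9.25-fold, interval from 7.37). Of the same list, 2 were higher in lymphatic cells, led by Ackr2, a scavenger of inflammatory CC chemokines (12.4-fold, 5.25 to 33.6). Vasoactive genes gave 4 and 3: the vasoconstrictor gene Edn1 was 47.7-fold higher in blood endothelial-like cells (8.44 to 1897, 1 lymphatic UMI), and Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, 9.91-fold higher in lymphatic cells (4.90 to 21.7). Growth factors gave 3 on the blood side, with Pdgfb 13.97-fold (5.90 to 43.4) and Hbegf 33.7-fold (5.92 to 1342, 1 lymphatic UMI), and 2 on the lymphatic side.

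Of 17 TGF-beta and BMP genes, 5 were higher on each side, while the list median leaned to lymphatic cells (log2 ratio 0.57, percentile 99.99). Bmp2 and the BMP inhibitor Smad6 were higher in blood endothelial-like cells by at least 6.24-fold and 6.55-fold against the floor (intervals from 4.92 and 5.17). Cytokines gave 3 and 3 of 8, with Tnf 26.8-fold higher in blood endothelial-like cells (4.69 to 1071, 1 lymphatic UMI). Of 6 MHC class II genes, 4 were higher in lymphatic cells and 0 in blood endothelial-like cells, with a median log2 ratio of 1.01, at percentile 99.95 of random lists. The class II sum was 2057 against 801 CPM, beside 1634 CPM in T cell-like and 937 CPM in smooth muscle-like cells, so much of it lies in the range of background. Complement genes gave 3 of 7 higher in lymphatic cells and 0 in blood (median log2 ratio 0.82, percentile 100), with a sum of 994 CPM beside 712 CPM in T cell-like cells. Interferon genes gave 1 lymphatic and 3 blood of 14, hypoxia genes 2 and 2 of 9, immediate early genes 0 and 1 of 16, and Wnt genes 0 and 1 of 3. Of 3 measured neurotensin system genes, Nts was the 1 that differed.

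Keeping called doublets turned the direction of Col8a1, 18.0-fold higher in blood endothelial-like cells (6.05 to 88.1, from 3 lymphatic UMIs), to a log2 ratio of 0.63, lowered Ptn to 2.74-fold and took Lox to 1.85-fold and Ptger4, at least 2.81-fold here (interval from 2.13), to 1.61-fold. Ptn was also 3.96-fold with another random seed and at resolution 0.5, and 4.02-fold at resolution 2. It was 3.96-fold with cluster 12 added to the blood side and 73.0-fold with cells weighted equally. The 39.6-fold size of Ptn thus depends on the clustering. Ccnb1 kept a 2-fold difference in 5 of 12 alternatives, the 2 cell filters that changed nothing among the 5, and was 1.14-fold at Leiden resolution 0.5. Of the 27 named genes called, 26 kept their direction and 23 a 2-fold difference in the alternatives that gave them a value; Edn1 and Smad6, among the 23, had too few UMIs to be called with 4000 variable genes. In at least 1 alternative 26 moved by more than 1.5-fold, and the Nts ratio ran from 2.72 to 5.54.

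**Figure D3:**
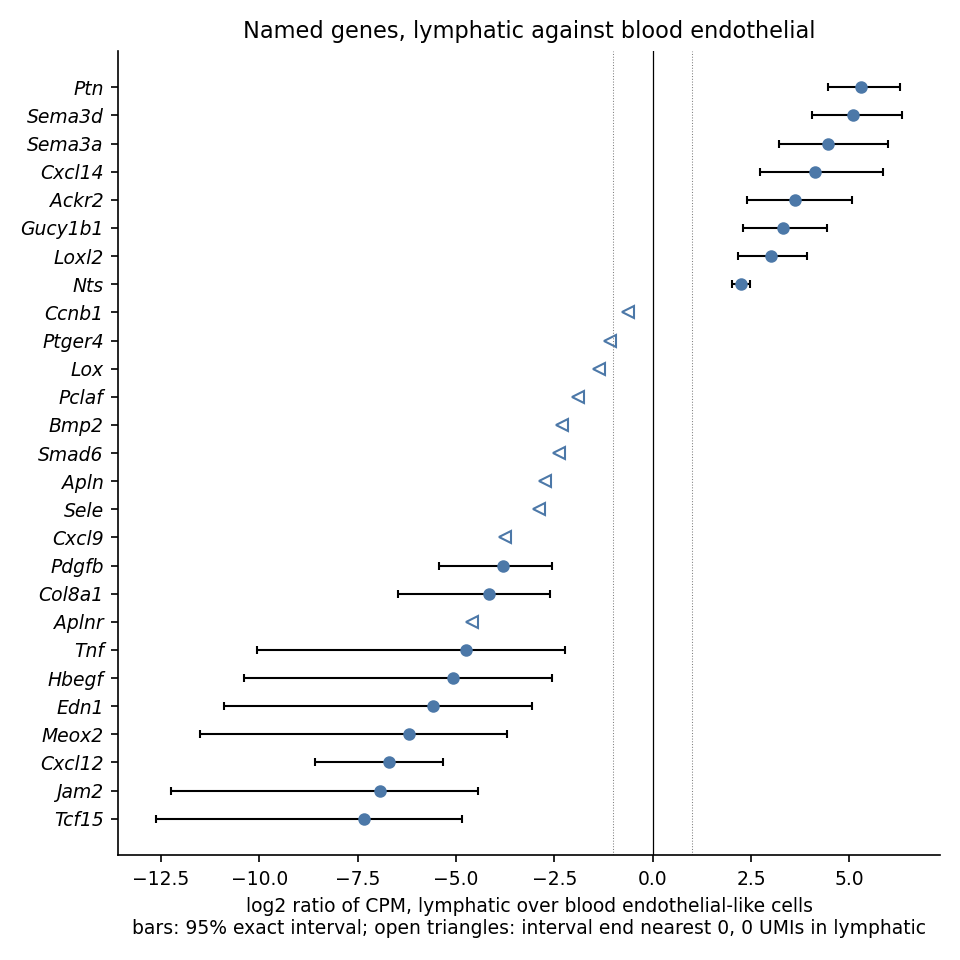
Log2 ratio of lymphatic over blood endothelial-like CPM for the named genes, with 95% exact intervals; open triangles mark the interval end nearest 0 for genes with 0 lymphatic UMIs, and dotted lines mark 2-fold. In the reported clustering, Ptn leads the lymphatic side at 5.31 and Tcf15 the blood side at -7.33.

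Fibroblast-marker clusters against all other cells asks which matrix, inflammatory and signalling genes the fibroblasts of the overloaded heart carried. Matrix genes were higher in them almost without exception: 28 of 30 passed, and their sum was 31068 CPM against 5447 CPM, 5.70-fold. Sparc, a collagen-binding matricellular protein, was 8119 CPM in these clusters (8090 to 8148), and Col3a1, a fibrillar collagen, 5106 CPM (5083 to 5129). The matrix list's median log2 ratio was 2.36, above all random lists. MHC class II genes were the opposite, with 8 of 8 lower: Cd74, the invariant chain, was 94.2-fold lower (92.2 to 96.2) and H2-DMb1, a peptide-loading chain, 89.2-fold lower. Free RNA from other cells was not subtracted, and many immune and endothelial genes were lower by a similar factor in this comparison. Free RNA would make these large folds too small, so their narrow intervals do not give their true size. They are not strict lower bounds either. Over the alternatives Cd74 ran from 70.3-fold to 104-fold lower and the chemokine gene Ccl22 from 39.6-fold to 128-fold lower. Of 303 list genes measured, 104 were higher in fibroblast-marker clusters, 119 lower and 80 neither.

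Of the signalling lists, TGF-beta and BMP, growth factor and Wnt genes were more often higher in fibroblast-marker clusters, and vasoactive genes were nearly even. TGF-beta and BMP genes were higher for 14 of 23 and lower for 1 (median log2 ratio 2.13). Growth factors gave 9 higher and 5 lower of 18, and Pdgfb was 65.2-fold lower (43.9 to 101) and Igf2 37.8-fold from 2 UMIs (9.98 to 320). Wnt genes gave 6 higher and 3 lower of 13, with the secreted Wnt modulator Sfrp2 10.6-fold higher (9.65 to 11.6) and the ligand Wnt9b 39.2-fold lower from 2 UMIs (10.4 to 332). Angiogenic genes gave 11 higher and 10 lower of 26, with a median log2 ratio of 0.50 (percentile 99.2), the endothelial receptors Tie1 and Robo4 being 72.0-fold (44.7 to 124) and 76.4-fold (20.6 to 638, 2 UMIs) lower. Vasoactive genes gave 8 and 7 of 19. The alpha-1A adrenergic receptor Adra1a was 15.7-fold higher on 22 UMIs against 1 (2.54 to 648), and the beta-1 receptor Adrb1 and the endothelin receptor Ednrb were 40.9-fold and 101-fold lower.

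Inflammatory lists leaned away. Cytokines gave 6 higher and 16 lower of 23, with Il1b 88.2-fold lower (81.7 to 95.5) and Arg1 103-fold lower (60.9 to 188). Chemokines gave 7 and 13 of 23: Ccl19, a lymphoid homing chemokine, was 16.1-fold higher (10.6 to 25.6) and Ccl24 86.0-fold lower (60.7 to 126). Ccl22 was 105-fold lower from 2 UMIs (28.6 to 876). Complement gave 6 and 7 of 15, with C1qa and the receptor C3ar1 91.5-fold and 96.4-fold lower. Leukocyte adhesion genes gave 4 and 12 of 20, with P-selectin (Selp) 66.4-fold lower (33.3 to 155). Interferon genes gave 0 and 5 of 16, hypoxia genes 1 and 5 of 13, with the carbonic anhydrase gene Car9 47.2-fold lower from 3 UMIs (15.7 to 233), and immediate early genes 1 and 2 of 16. Lipid genes gave 2 and 6 of 13, including the sterol transporter Abcg1 (19.1-fold lower) and Pparg (16.4-fold lower). Nts was 55.9-fold lower (40.7 to 78.9), Sort1 1.74-fold higher (1.44 to 2.10) and so under the 2-fold rule. Of 7 neurotensin system genes, 1 was higher and 1 lower.

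Of 20 cell cycle genes, 18 were lower in fibroblast-marker clusters, led by Ccna2 (61.2-fold, 34.7 to 119) and Ube2c (51.4-fold, 36.2 to 75.4). These sizes hold for a single clustering. In all 7 alternatives that clustered the cells anew, another random seed among them, the log2 ratio of Ccna2 went from -5.93 to between -1.22 and -0.70 and that of Ube2c from -5.68 to between -2.29 and -1.79. With the mixed clusters counted under their leading list, which adds the cycling cluster 17 to the fibroblasts, they were -1.29 and -2.37. At Leiden resolution 0.5, Mmp3 (10.8-fold higher, 9.15 to 12.8) and Ccl19 turned to log2 ratios of -0.35 and -0.81. Ccl19 was 1.65-fold with 15 principal components, and at resolution 0.5 Sfrp2 dropped to 1.22-fold, Ccna2 to 1.63-fold, and the matrix ratio was 3.36. The matrix ratio reached 11.3 with mixed clusters left out. Of the 27 named genes called, 13 moved by more than 1.5-fold in at least 1 alternative, Adra1a from 4.28-fold to 49.7-fold.

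The matrix programme was uneven among the fibroblast-marker clusters, which had been made without the matrix genes; the genes named here were chosen after their values were seen. Cluster 3 was highest for 17 of the 30 matrix genes, with 42486 CPM for the list against 23026 CPM in cluster 19. It held the periostin gene Postn at 2458 CPM, 11.04-fold over cluster 6 (10.3 to 11.8), and Cthrc1, Thbs4 and the connective tissue growth factor gene Ccn2 at 213, 338 and 2726 CPM. Meox1, a homeobox transcription factor of activated fibroblasts, was 628 CPM there against 103 CPM in cluster 2. Cluster 4 was highest for 5 matrix genes, including the elastic fibre genes Eln (1798 CPM) and Fbln1 (3506 CPM). Cluster 19 was highest for 4, including Comp (396 CPM) and Fmod (340 CPM), and its Wnt list reached 2665 CPM, with the Wnt inhibitor Wif1 alone at 940 CPM. Cluster 2 was highest for the chemokine list (7896 CPM) and carried C3 at 1229 CPM, against 140 CPM in cluster 3. The ratio of the highest to the lowest cluster for the matrix list was 1.85 and ran from 1.53 to 2.77 over the alternatives.

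**Figure D4:**
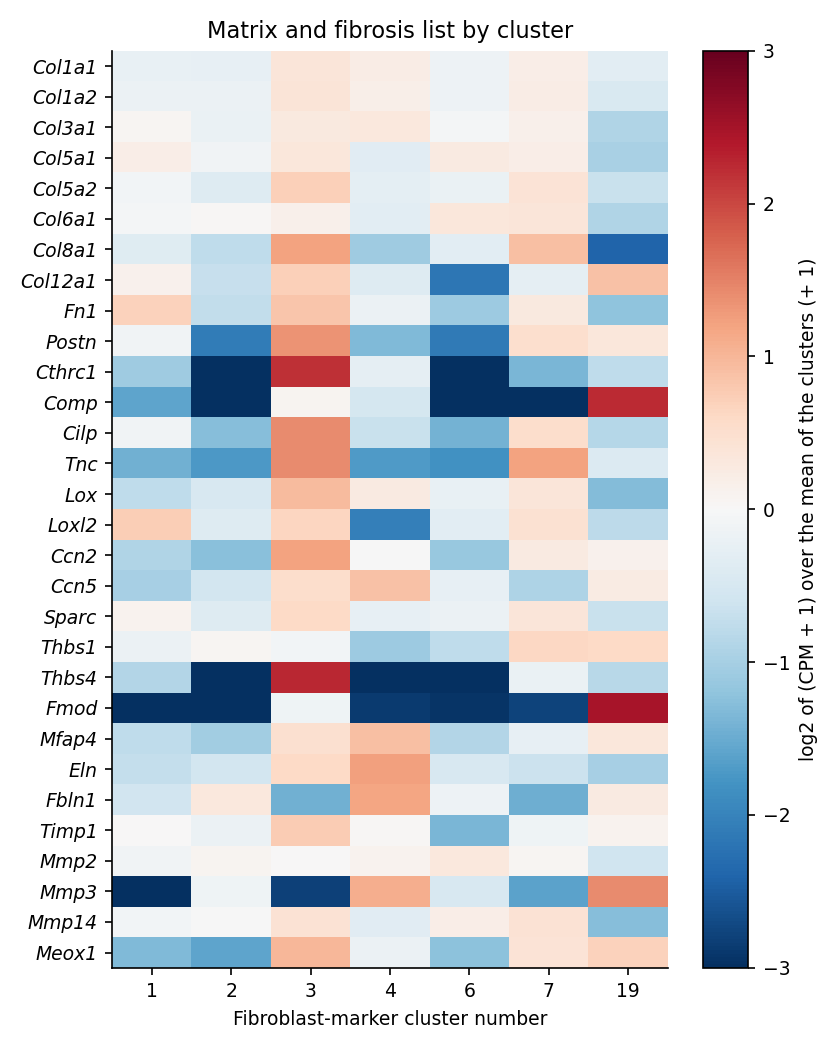
Matrix and fibrosis list genes by fibroblast-marker cluster, as log2 of CPM (1 added) over the mean of the 7 clusters, with the colour scale ending at 3 in either direction. Cluster 3 is highest for 17 of the 30 genes and cluster 19 for 4.

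Macrophage-like against monocyte-like cells describes the myeloid compartment under overload. Complement separated these classes, while class II presentation differed on average but not in every cluster. C1qa and C1qc, chains of the complement initiator C1q, were 14.3-fold (13.5 to 15.1) and 13.7-fold (12.9 to 14.6) higher in macrophage-like cells, and the complement sum was 21844 against 2690 CPM. Over the alternatives C1qa ran from 9.03-fold to 51.8-fold and C1qc from 9.24-fold to 42.4-fold. Class II genes were higher for 5 of 8 and lower for 0, with a sum of 53944 against 19099 CPM. By cluster, the class II sum was 82739.5 and 81982 CPM in macrophage-like clusters 8 and 9 but 27447 CPM in cluster 5. Only macrophage-like cluster 25, at 9848 CPM, was below monocyte-like cluster 10, at 22159 CPM. The other monocyte-like cluster, 21, had 7850 CPM, below every macrophage-like cluster. Monocyte-like cells had more of Itgal, a leukocyte integrin chain (14.6-fold, 12.1 to 17.6). Itgal was among the 10 leading genes of cluster 21 but not of cluster 10. Of 251 list genes measured, 71 were higher in macrophage-like cells, 59 in monocyte-like cells and 121 neither.

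Complement as a list gave 7 higher and 4 lower of 15 in macrophage-like cells, and C3 was 7.10-fold higher in monocyte-like cells (6.13 to 8.23). Chemokines gave 10 and 1 of 20: the B cell attractant Cxcl13 was 57.3-fold higher in macrophage-like cells (19.5 to 278, 3 monocyte UMIs), and Ccl22 at least 2.53-fold against the floor (interval from 1.95, under 2-fold). Growth factors gave 8 and 1 of 12, with Pdgfc 26.4-fold higher (4.65 to 1052, 1 monocyte UMI). Cytokines gave 4 and 6 of 20, with the stress cytokine Gdf15 7.94-fold higher in macrophage-like cells (6.71 to 9.45) and Ifng 5.54-fold higher in monocyte-like cells on 12 UMIs (2.19 to 14.3). Adhesion genes gave 3 and 4 of 15, the scavenger receptor Stab1 being 11.8-fold and Vcam1 5.43-fold higher in macrophage-like cells. Lipid genes gave 3 and 3 of 11, with a median leaning to monocyte-like cells (log2 ratio -0.71, percentile 0.13) and the phospholipid transfer protein Pltp 4.99-fold higher in macrophage-like cells (4.51 to 5.54). Of 20 cell cycle genes, 19 were higher in macrophage-like cells, including Birc5 (57.0-fold, 15.7 to 472, 2 monocyte UMIs; 5.03-fold at Leiden resolution 0.5). Cluster 23, with 74 of the 1846 cells, had a cell cycle sum of 5171 CPM, while the other macrophage-like clusters had 195 to 253 CPM and the monocyte-like class 120 CPM.

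On the monocyte side, interferon genes gave 6 higher and 0 lower of 16 (7666 against 3327 CPM) and hypoxia genes 4 and 0 of 12 (2312 against 1250 CPM). Of 26 matrix genes, 14 were higher in monocyte-like cells, among them Thbs1, an activator of latent TGF-beta (5.46-fold, 5.14 to 5.80). The matrix sum was 3100 CPM in monocyte-like cells, 1255 CPM in macrophage-like cells, 1566 CPM in B cell-like cells and 1522 CPM in T cell-like cells, so part of the monocyte level lies within the background seen in lymphocytes. By cluster, the matrix sum was 5551 CPM in monocyte-like cluster 21 and 2434 CPM in cluster 10. It was 7122 CPM in macrophage-like cluster 25 and 718 to 1351 CPM in the other macrophage-like clusters. Angiogenic genes gave 4 higher in macrophage-like and 6 in monocyte-like cells of 17, with Flt1 15.4-fold higher in monocyte-like cells (7.92 to 32.2) and Vegfb 5.43-fold higher in macrophage-like cells. Vasoactive genes gave 3 and 4 of 13, with the adenosine receptor gene Adora2a 7.33-fold higher in monocyte-like cells and Adrb1 5.05-fold higher in macrophage-like cells. TGF-beta and BMP genes gave 4 and 3 of 20, with a median leaning to monocyte-like cells (log2 ratio -0.46, percentile 0.14), although Bmp2 was 5.15-fold higher in macrophage-like cells. Wnt genes gave 0 and 2 of 5, with Rspo1 21.2-fold higher in monocyte-like cells (7.90 to 71.6), and immediate early genes 0 and 0 of 16 (median log2 ratio 0.28, percentile 99.8). The Wnt sum was 136 CPM in monocyte-like cluster 21 but 36.0 CPM in cluster 10, within the 8.94 to 42.9 CPM of the macrophage-like clusters. Sort1 was 5.81-fold higher in monocyte-like cells (3.64 to 9.33), Thop1 was the other neurotensin system gene that differed, and Ntsr1 and Ntsr2 had 0 UMIs on both sides.

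At Leiden resolution 0.5, the number of genes higher in monocyte-like cells dropped from 59 to 30, Itgal to 2.48-fold and Cdc20, at least 11.9-fold higher in macrophage-like cells here (interval from 9.58), to 1.32-fold, Ccl22 to 1.54-fold, and Ccl11 and Mmp3, 9.45-fold (5.56 to 16.5) and 7.56-fold (3.38 to 17.7) higher in monocyte-like cells here, lost their call: Ccl11 turned to the macrophage side (log2 ratio 2.06, 0.15 to 5.14), and the interval of Mmp3 included 0 (0.89, -1.10 to 4.00). With 15 principal components, Ereg, at least 2.24-fold higher in macrophage-like cells here (interval from 1.71), turned to the monocyte side and the class II ratio moved from 2.82 to 5.02. Ereg was past 2-fold in 7 of 11 alternatives, the 2 cell filters that changed nothing among the 7. Of the 27 named genes called, 23 moved by more than 1.5-fold in at least 1 alternative.

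Cells with cell cycle transcripts differed by class. With at least 2 UMIs over the list at equal depth, 15.4% of T cell-like cells (11.9 to 19.4%), 14.5% of NK or innate lymphoid-like cells (8.70 to 22.2%) and 13.2% of blood endothelial-like cells (9.01 to 18.4%) counted as cycling. Shares were 10.3% in pericyte-like cells (4 of 39; 2.87 to 24.2%), 9.10% in macrophage-like cells (7.83 to 10.5%) and 8.68% in cluster 12 (5.30 to 13.2%). They were 2.01% in fibroblast-marker clusters (1.63 to 2.45%) and 1.92% in monocyte-like cells (0.832 to 3.75%), and 3 of 70 lymphatic cells were positive (4.29%, 0.893 to 12.02%). Dendritic cell-like and B cell-like cells had 6.74% and 5.26%. Pclaf and Rrm2, genes of DNA replication, were 223 and 153 CPM in T cell-like cells. The mixed cluster 17 held 114 cycling cells of 161 (70.8%). Counting it and the other mixed clusters whose leading list was the fibroblast list with the fibroblasts raised their share to 4.24% (3.70 to 4.84%). In the 7 alternatives that clustered the cells anew the fibroblast share was 4.25 to 4.74%, so the value of 2.01% depends on cluster 17 being set apart. Without 10 cells rich in cardiomyocyte transcripts, the other 151 cells of cluster 17 class as fibroblast-marker cells. The 2.01% thus leaves out cycling cells that class with the fibroblasts once those 10 are set aside. At Leiden resolution 0.5 the T cell share was 4.57% (2.11 to 8.50%) and the dendritic cell share 30.2%, so the order of the classes holds for the reported clustering. The level depends on the minimum: with 1 UMI in place of 2 the fibroblast share was 16.1% and the T cell share 39.5%, and at 3 UMIs they were 0.210% and 9.28%.

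Summed by class, the functional lists were highest in different parts of the pool. Class II presentation was highest in dendritic cell-like cells at 88135 CPM, with Cd74 and H2-Aa at 50066 and 15935 CPM. Chemokines were highest in NK or innate lymphoid-like cells at 21212 CPM, where Ccl5 alone was 16964 CPM and Ccl4 2361 CPM. Among the macrophage-like clusters, cluster 25 reached 29235 CPM and the others 7512 to 15713.5 CPM. Monocyte-like cells had the highest levels of cytokines (6512 CPM; Il1b 3115 and Lgals3 2416 CPM), of interferon-response genes (Ifitm3 6068 and Isg15 412 CPM) and of hypoxia genes (2312 CPM, 2253 to 2373; Ldha 708 and Aldoa 612 CPM), the last level with pericyte-like (2168 CPM, 1965 to 2386) and lymphatic endothelial-like cells (2133 CPM). Clusters within these classes differed: the cytokine sum was 14311 CPM in macrophage-like cluster 25 and 7429 CPM in cluster 8. Monocyte-like clusters 10 and 21 had 7125 and 4261 CPM, and the other macrophage-like clusters 2137 to 2905 CPM. Hypoxia genes reached 2909 CPM in cluster 25, 2454 and 1792 CPM in clusters 10 and 21, and 1033 to 1411 CPM in the other macrophage-like clusters. Macrophage-like cells had the highest lipid sum (14014 CPM), led by Apoe at 12484 CPM, and C1qb at 7972 CPM. Cluster 12 was highest for angiogenic genes (4935 CPM; Ramp2 1671 and Nrp1 849 CPM) and for adhesion genes (Vcam1 1135 and Icam2 625 CPM). TGF-beta and BMP genes were level in cluster 12 (5150 CPM, 5032 to 5269) and fibroblast-marker clusters (5108 CPM, 5085 to 5130). In cluster 12 Eng had 1762 CPM, and Fstl1 had 765 CPM against 1279 CPM in all other cells. Smooth muscle-like cells led the vasoactive list (2834 CPM) with Gucy1a1 at 1417 CPM and Gucy1b1 at 976 CPM, and the immediate early list with Fos at 9573 CPM, while Junb, at 4102 CPM, was below the 4826 CPM of all other cells. Growth factors were level in pericyte-like cells (1614 CPM, 1440.3 to 1804; Ptn 895 and Pdgfa 248 CPM) and cluster 12 (1409 CPM, 1348 to 1472), while Wnt genes were level in mesothelial or epicardial-like cells (748 CPM, 648 to 859) and fibroblast-marker clusters (744 CPM). In the mesothelial class Rspo1 had 298 CPM, and Sfrp1, at 134 CPM, was below the 238 CPM of all other cells. Immediate early genes, which tissue digestion can induce, were between 12331 CPM in pericyte-like and 35215 CPM in smooth muscle-like cells.

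**Figure D5:**
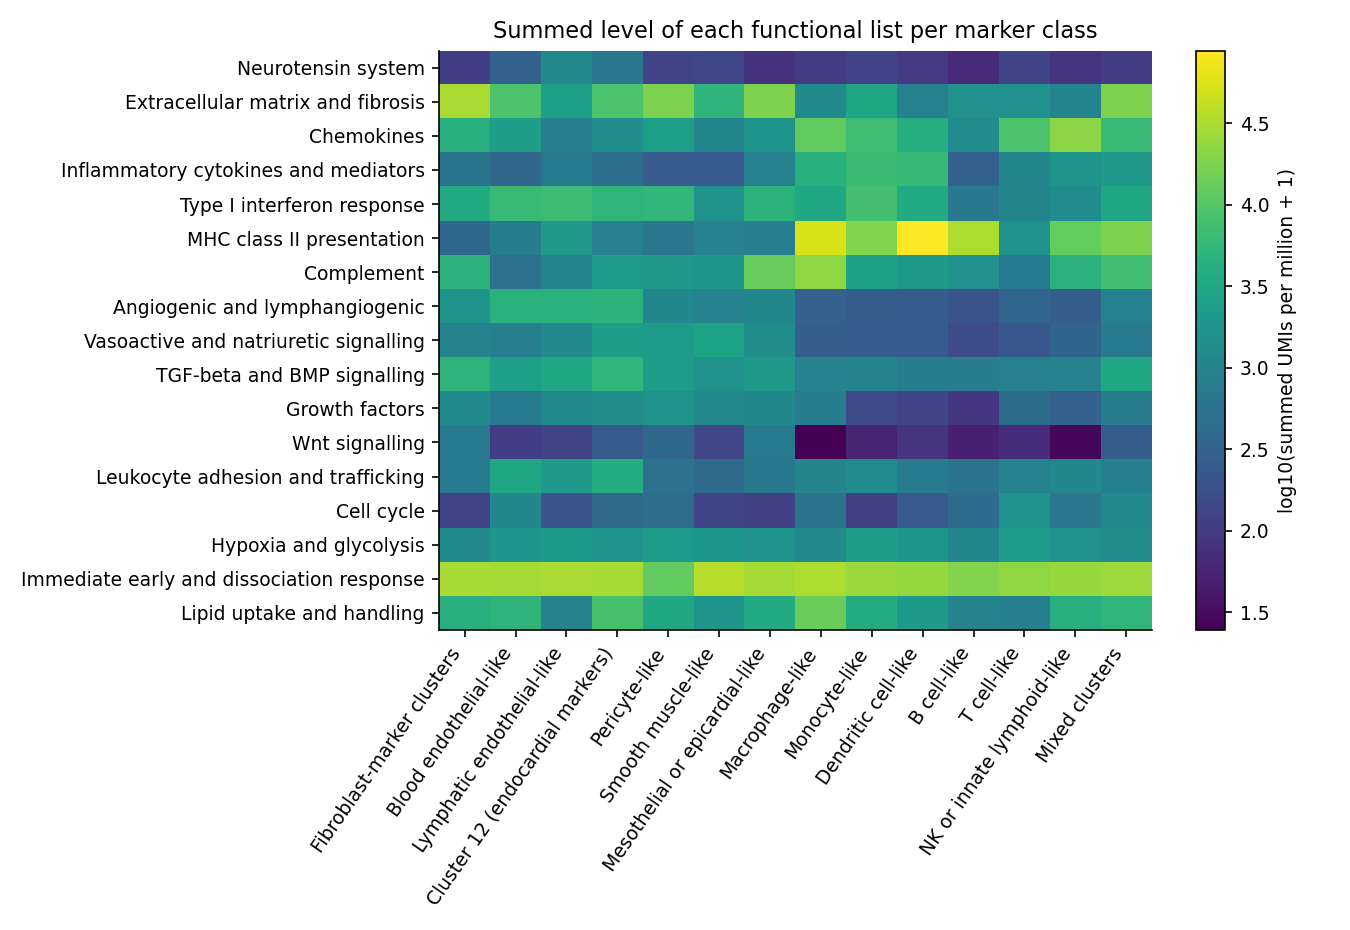
Summed level of the 17 functional lists in each marker class, as log10 of CPM (1 added). Class II presentation peaks in dendritic cell-like cells at 88135 CPM and the matrix list in fibroblast-marker clusters at 31068 CPM.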

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

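All tests in this part were chosen after the result was seen, except the comparison of fibroblast-marker cells with and without Esr1.

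The CreERT2 transgene is a feature that no comparison uses, and it gave 64 UMIs, above the limit that a count of 0 allows. Lymphatic endothelial-like cells held 24 of them in 13 of 70 cells (64.8 CPM), cluster 12 held 11 and blood endothelial-like cells 1. Fibroblast-marker clusters held 26 in 26 cells (0.682 CPM), and 3121 immune cells held 0. Genotype was not read from these counts.

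Free RNA would give immune cells the fibroblast rate, or 12.8 UMIs where 0 were found, and the lower bound of the ratio of fibroblast-marker to immune CPM was 3.22. The 26 fibroblast-marker cells held 0 Ccl21a UMIs, and 21 of them had Pdgfra. Reads shared with the estrogen receptor gene Esr1 were tested in 2 ways. Fibroblast-marker cells with an Esr1 UMI had 1.21 times the CreERT2 rate of those without (0.0296 to 7.41), which rests on 1 UMI and decides nothing by itself. Across classes, Esr1 would predict 6.81 CreERT2 UMIs in immune cells against the 0 found, which argues against it as the whole source. No biological explanation was tested.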

How the results depend on the processing

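All alternatives here were planned before the data were examined, except another random seed and the other treatments of mixed clusters, of cluster 12 and of fibroblast clusters, which were chosen after seeing the data. The 2 cell filters removed 0 barcodes and moved nothing. Of 1002 ratios of named genes over the alternatives, 826 stayed within their interval, 170 moved and 6 reversed. Of 539 other values, 381 stayed and 158 moved. The stayed counts include the 2 cell filters, whose values could not differ, and so overstate stability. A gene with 0 UMIs on a side has an interval with no limit in that direction, which also makes staying easier. Counts of genes were taken to stay within 1.5 times the reported count, which is wide: genes higher in lymphatic cells numbered 28 to 46 (40 reported) and in monocytes up to 82 (59 reported). Where values moved, the cause was not tested, except where the minimum, the thinning or the cells counted changed by construction.

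The fibroblast share of 52.9% was 45.4% at Leiden resolution 0.5, 54.5% at resolution 2, 51.7% with 15 principal components, 54.6% with another seed, 55.4% with mixed clusters under their leading list and 56.1% with them left out. Lymphatic Nts was 1026 CPM with doublets kept and 1277 CPM with cells weighted equally, and the endothelial share of Nts 96.1% with mixed clusters left out.

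The Nts log2 ratio of lymphatic over blood endothelial-like cells was 1.63 with doublets kept, 1.54 with 4000 variable genes, 1.70 with list genes allowed, 1.44 and 1.51 at resolutions 0.5 and 2, 2.01 with 15 principal components, 1.49 with another seed, 2.47 with equal weights and 1.44 with cluster 12 added to the blood side, always below the reported 2.24 except with equal weights. Col8a1 reversed to 0.63 with doublets kept.

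The fibroblast cycling share of 2.01% was 4.31% with doublets kept, 4.29% with 4000 variable genes, 4.26% with list genes allowed, 4.74% and 4.25% at resolutions 0.5 and 2, 4.34% with 15 principal components, 4.27% with another seed and 4.24% with mixed clusters under their leading list. It was 0.923%, 5.82% and 24.3% with thinning to 1000, to 3000 and none, and 16.1% and 0.210% with minimums of 1 and 3 UMIs. The T cell share was 4.57% at resolution 0.5, 34.1% and 36.6% with thinning to 3000 and none, and 39.5% and 9.28% with minimums of 1 and 3.

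The matrix log2 ratio of the highest over the lowest fibroblast cluster (0.88) was 0.93 with doublets kept, 1.47 with list genes allowed, 0.61 and 1.40 at resolutions 0.5 and 2, 0.64 with 15 principal components, 1.12 with another seed and 0.97 with equal weights. The fibroblast matrix level was, in the same order, 30914.5, 31198, 30649, 30940.3, 30928, 30945 and 29158 CPM, and 33443 CPM without mitochondrial and ribosomal protein genes.

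At resolution 0.5, log2 ratios reversed for Mmp3 (-0.35) and Ccl19 (-0.81) in fibroblasts and for Mmp3 (0.89, with an interval that includes 0) and Ccl11 (2.06) in macrophages over monocytes, and genes higher in monocytes numbered 30. Ereg reversed to -2.85 with 15 principal components.

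No value was given for smooth muscle in 5 alternatives, for B and NK cells with doublets kept, for the endocardial class at resolution 0.5 and for dendritic cells with 15 principal components, where no such class was found. Ccl22, Lox, Edn1, Ptger4, Smad6, Ifng or Adra1a fell under 20 UMIs in some. The alternatives for control against knockout mice (size factors of DESeq2, no low-count filter, leaving out each mouse) were not run, since that comparison was not made. Counts limit the small classes: 70 lymphatic cells left 112 list genes with too few UMIs.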

Other observations

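All tests in this part were chosen after the result was seen, as were the genes named in its first paragraph.

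The macrophage-like cells were not a single state 7 days after TAC. Cluster 25 (69 cells) carried Arg1, an arginine-degrading enzyme of wound macrophages, at 1608 CPM (1496 to 1726), against 5.18 CPM or less in the other macrophage-like clusters, with Spp1 (osteopontin) at 5478 CPM and the neutrophil attractant Cxcl2 at 18218 CPM. Its class II sum was 9848 CPM, beside 82739.5 CPM in cluster 8 and 81982 CPM in cluster 9. Cluster 5 (779 cells) held Timd4 at 130.4 CPM, Gas6 at 607 CPM, Igf1 at 427 CPM and Ccl8 at 618 CPM, a resident-type set with little Ccr2 (72.4 CPM, against 355 CPM in cluster 8 and 394 CPM in cluster 9). Cluster 8 joined high class II to Il1b at 4190 CPM, where the value is 1288 CPM in cluster 9. Cluster 23 (74 cells) stood out for its cell cycle sum of 5171 CPM. Among monocyte-like cells, Isg15 was 504 CPM in cluster 10 and 72.8 CPM in cluster 21.

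Nts outside the lymphatic class was weighed against carry-over from lymphatic cells. The blood endothelial-like cluster and cluster 12 held 1093 Nts UMIs and 6 Ccl21a UMIs, where the lymphatic cluster had 422 and 9458. At that ratio, lymphatic free RNA accounts for 0.0245% of their Nts. With every cell holding a UMI of Prox1, Mmrn1, Reln or Ccl21a left out, 73.0% of the Nts UMIs were left (99.0% in the blood endothelial-like cluster and 63.8% in cluster 12). Transcription of Nts in some blood endothelial or endocardial cells may be the source, as a hypothesis found and tested on the same cells, and no biological explanation was tested.

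Cluster 17 carried cardiomyocyte transcripts although the suspension was made of other cells. Of its 1975 cardiomyocyte marker UMIs, 97.9% lay in 10 of 161 cells, with 640 in the highest, which argues against free RNA spread over the cluster. Of these 10 cells, 5 held fewer than 10 UMIs of 5 fibroblast genes, which argues against doublets with fibroblasts for those, and doublets stay open for the other 5. Without the 10 cells, the remaining 151 class as fibroblast-marker cells. No biological explanation was tested.

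Of sex-linked genes, Xist had 16 UMIs and Ddx3y 6617 UMIs in the pool.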
